A study of Mus musculus with 614 samples.

How the data were processed

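Single cells were sorted by surface markers from bone marrow and blood of adult C57BL/6J mice and captured on microfluidic chips for full-length cDNA amplification and transposon-based library preparation. Per the labels 614 cells fall into 12 gates, and all 614 were used. The deposited values are TPM per gene symbol and cell, made by the authors with RSEM 1.2.19 on GRCm38. The aligner and the annotation are not given in the sources used here. The totals per cell lay between 997617 and 1000000, 43280 symbols were listed, 15695 of them were 0 in all cells and 44 looked like averages of several entries. TPM keep no read counts, so the depth and the counting precision of a level are unknown; genes at 1 TPM or more per cell, from 1001 to 9977, stand in for depth.

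Each gate was treated as 1 sample. No label names an animal, a culture or a pool, and the replicate number of a cell only names the cell. Therefore no p-value, standard error or count of changed genes was computed, and all SDs are over cells. Per gene and contrast, the value was the difference between gates in the mean over cells of log2(TPM + 1), with a pseudocount of 1. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the limit that 3 counts allow; both cover counting error only. Of 14 contrasts 5 were chosen as main ones. Blood pre-DC were set against the mean of the 4 marrow pre-DC gates, each with equal weight. No doublet caller was run; leaving out the 5% of cells with the most genes in each gate was tried instead. Transcripts of proteins used for sorting were used as a check of the labels and are not findings between gates that differ in that protein. The check was mixed. At 1 TPM or more Siglech was in 44.3% of SiglecH-Ly6C- and 51.5% of SiglecH-Ly6C+ pre-DC, at means below those of the SiglecH+ gates. Il7r was in 56.9% of CDP, sorted as negative for its protein.

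Before the data were examined, the contrasts, the 19 gene lists, the alternatives and the rule for named genes were fixed. The rule takes the 10 largest differences in each direction for a main contrast and the 5 largest for a secondary one, among genes at 1 TPM or more in at least 50% of the cells of the higher gate. It leaves out predicted genes, pseudogenes, mitochondrial, ribosomal protein and sex-linked genes, antigen receptor segments and sort markers. Of the genes this rule names, 1 is not reported here. Besides these, the 2 highest and 2 lowest members of a list and a fixed set of lineage genes may be named. The lists cover pDC, cDC, MHC class II, granule, monocyte, early lymphoid, B lineage, multipotency, S phase, G2/M, interferon, immediate-early, erythroid, platelet, T and NK cell, basophil and mast cell, neutrophil, macrophage and plasma cell genes. A list's value is the median difference of its members, with the number higher and lower. Its percentile among 10000 random lists, matched in size and in 20 bins of expression over genes in 5% or more of cells, was used to decide whether it had a direction.

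The CLP-to-GMP position used 50 genes per side, chosen on odd-numbered CLP and GMP cells and scaled on the even-numbered ones. Sort markers and cell cycle genes were left out. Profile similarity was the Spearman correlation across genes at 1 TPM or more in 20% of the cells of any gate. Library numbers in the labels form 9 runs, which were taken as possible batches. CLP, GMP and pre-pro-B cells share 1 run, CDP and most pDC another, and SiglecH+Ly6C- pre-DC are divided between runs shared with SiglecH+Ly6C+ and with SiglecH-Ly6C- pre-DC. LMPP, SiglecH-Ly6C+ pre-DC, blood pre-DC and cMoP each have a run of their own. Transcript lengths and coordinates came from GENCODE M21 on GRCm38, which held 39469 of the symbols (91.2%).

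The alternatives were pseudocounts of 0.1 and 10, the log2 of the mean TPM, median-of-ratios size factors over 496 genes, leaving out cells under 2000 genes, single number runs, other detection thresholds, other sizes and scales of the position and other forms of the similarity. Added after seeing the data were leaving out genes under 200 nucleotides, a threshold of 100 TPM, subsets of cells by Xist and Y-linked transcripts, the position without immediate-early genes, and leaving out the GMP cells with Ly6d above 1000 TPM. The 29 list values treated as the main answers of the contrasts were also picked after the values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with seed 1. The steps were tested on simulated data, in which 200 genes were changed 8-fold in a random part of the GMP cells. All 20 named genes were among those changed. However, among well expressed genes the raised ones (63) came back at a median of 2.02 and the lowered ones at -3.38. Of the 100 genes chosen for the position 68 were changed ones. Of 100 unchanged lists, themselves drawn at random, 3 lay outside the central 95% of random lists. This does not test lists whose members vary together. Unchanged well expressed genes shifted by -0.48, because TPM are shares of a fixed total.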

Results

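Single-cell messenger RNA profiles were measured in 598 mouse bone marrow cells and 16 blood cells, each captured and amplified on a microfluidic chip and sequenced as its own library. The cells came from 12 sort gates of adult C57BL/6J mice, 11 from bone marrow and 1 from blood. Early progenitors were 65 lymphoid-primed multipotent progenitors (LMPP), 51 granulocyte-monocyte progenitors (GMP), 48 common lymphoid progenitors (CLP), 66 common monocyte progenitors (cMoP) and 58 CD115-negative common dendritic cell progenitors (CDP). Dendritic precursors (pre-DC), sorted as CD11c-positive and MHC class II-negative, were divided by the surface proteins SiglecH and Ly6C into 45 SiglecH+Ly6C+, 68 SiglecH-Ly6C+, 70 SiglecH-Ly6C- and 70 SiglecH+Ly6C- cells. The other gates held 27 plasmacytoid dendritic cells (pDC), 30 pre-pro-B cells and 16 blood pre-DC. Values were TPM, a length-scaled share of each cell's transcripts that keeps no read depth, so the depth is unknown and the number of genes at 1 TPM or more stands in for it. Its median per cell ran from 3280 in CLP to 6671 in cMoP, and the median mitochondrial share of TPM from 3.03% in pre-pro-B cells to 9.38% in pDC. Each gate counted as 1 sample because no label names an animal, so no test of a difference between gates was made. The SD after each mean is over cells. Unless stated otherwise, levels are mean log2(TPM + 1) and differences are between gate means on that scale. A gene list is called undirected where its median lay within the central 95% of matched random lists, which ignore that members of a list vary together.

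Ly6d, which encodes a surface protein of lymphoid progenitors, differed between gates both in presence and in level. Its median was 17387 TPM in pre-pro-B cells, 4791 TPM in SiglecH+Ly6C- pre-DC, 3225 TPM in pDC and 553 TPM in CLP. GMP had a median of 18.8 TPM, CDP 6.89 TPM and SiglecH+Ly6C+ pre-DC 7.48 TPM, and the medians of the remaining gates were 0. At 1 TPM or more Ly6d was present in 100% of GMP cells (exact Clopper-Pearson 95% interval 93.0 to 100) and in 100% of CLP cells (92.6 to 100). At 100 TPM or more it was present in 3.92% of GMP cells (0.478 to 13.5), 60.4% of CLP cells (45.3 to 74.2), 29.3% of CDP (18.1 to 42.7) and 88.6% of SiglecH+Ly6C- pre-DC (78.7 to 94.9). The low GMP level occurred in a library number run where some genes abundant in another gate were detected at low level in many cells. Shares at 100 TPM, a threshold chosen after the values were seen, are therefore given beside those at 1 TPM. Low levels also occurred in other gates sharing a run with a gate high in Ly6d. From 1 to 100 TPM the share fell from 87.9% to 29.3% in CDP and from 88.9% to 28.9% in SiglecH+Ly6C+ pre-DC. In SiglecH-Ly6C- pre-DC it fell from 44.3% to 5.71%. LMPP, cMoP, SiglecH-Ly6C+ and blood pre-DC, each with its own run, had at most 6.25% at 1 TPM. For GMP, a test of carried-over reads that included Ly6d, given further below, did not decide the cause. In the other gates the cause of the low levels was not tested. Ly6d was seen in 0 of 65 LMPP cells, which allows a share of up to 4.62%, in 1 of 66 cMoP cells and in 1 of 16 blood pre-DC. These intervals and floors cover counting error only.

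**Figure D1:**
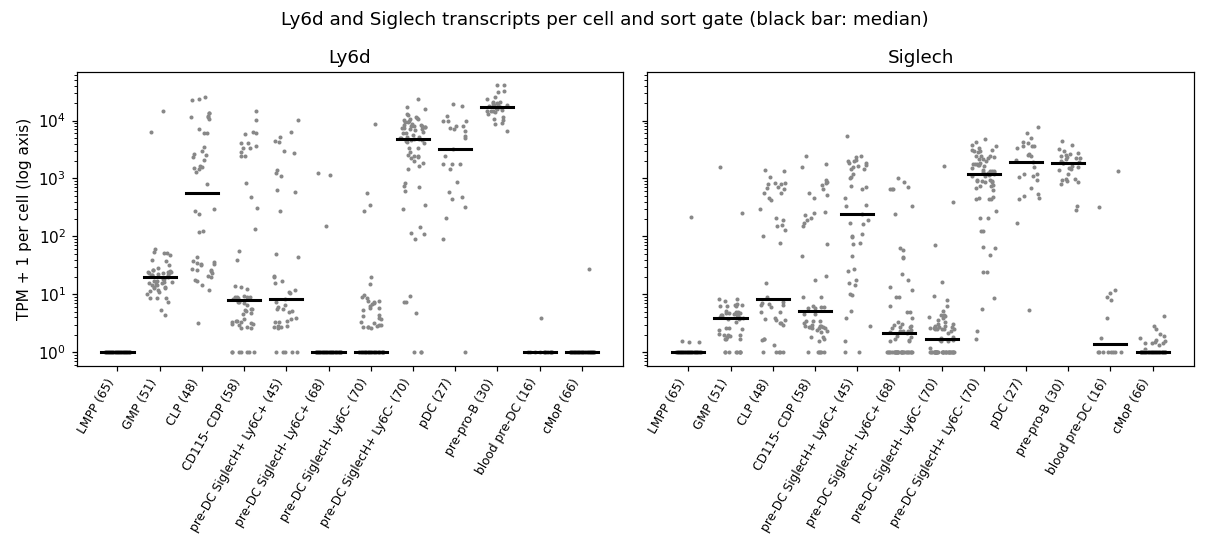
Ly6d (left) and Siglech (right) in each cell as TPM + 1 on a log axis, by sort gate with the number of cells in parentheses; points are cells and black bars are medians. CLP, CDP and SiglecH+Ly6C+ pre-DC each held cells above 1000 TPM of Ly6d and cells below 100 TPM.

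Ly6d and Siglech, the transcript of a receptor of pDC and their precursors, were both at 100 TPM or more in 35.4% of CLP cells (17 of 48, interval 22.2 to 50.5), against 26.4% from the product of the single shares. The same pair was present in 20.7% of CDP (11.2 to 33.4, product 9.10%), 24.4% of SiglecH+Ly6C+ pre-DC (12.9 to 39.5), 80.0% of SiglecH+Ly6C- pre-DC (68.7 to 88.6) and 88.9% of pDC (70.8 to 97.7), the last 3 sorted on SiglecH. Pre-pro-B cells had the highest share of any gate, 30 of 30 cells (88.4 to 100%). The remaining gates had at most 3.92%. In CLP a further 12 cells had Ly6d without Siglech and 4 had Siglech without Ly6d at that level. Ly6d together with Il7r, the receptor chain for interleukin 7, reached 100 TPM in 8 of 48 CLP cells, 9 of 58 CDP and 14 of 27 pDC. It also did so in 21 of 70 SiglecH+Ly6C- pre-DC, 10 of 30 pre-pro-B cells and 2 cells each of SiglecH+Ly6C+ and SiglecH-Ly6C- pre-DC. CLP were sorted as positive and CDP as negative for the Il7r protein, so these counts are no difference between gates. Ly6d together with Zbtb46, a transcription factor of conventional dendritic cells (cDC), did so in 2 SiglecH+Ly6C+ pre-DC. In the other gates 0 cells did. The product of the single shares was 2.57% in SiglecH+Ly6C+ pre-DC and at most 0.327% in the other gates. The zeros therefore cannot show whether the 2 genes exclude each other. At 1 TPM the pair was present in 40% of SiglecH+Ly6C+ pre-DC (product 41.5%) and 22.9% of SiglecH+Ly6C- pre-DC (product 25.98%). It was present in 21.4% of SiglecH-Ly6C- pre-DC (product 19.6%) and 15.5% of CDP (product 15.2%). On GRCm38 Ly6d lies on chromosome 15 from 74762056 to 74763620 and Siglech on chromosome 7 from 55768178 to 55778925.

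The comparison of CLP with GMP set the lymphoid against the myeloid progenitor within 1 library number run. Each gate held an unbroken block of numbers in that run, so gate and block cannot be told apart. Dntt, the polymerase that adds nucleotides at antigen receptor joints, averaged 9.53 ± 3.30 (SD, 48 cells) in CLP and 1.69 ± 0.84 (SD, 51 cells) in GMP. Elane, the neutrophil elastase gene, averaged 3.26 ± 1.42 in CLP and 12.79 ± 1.50 in GMP, and Mpo, the myeloperoxidase gene, 5.76 ± 2.36 and 13.28 ± 1.40. Tcf4, the transcription factor required for pDC, was higher in CLP by 2.35, whereas Irf8, a transcription factor of dendritic cells and monocytes, had a difference of -0.48 but the higher mean TPM in CLP (1656, against 352 in GMP). Dntt lies on chromosome 19 from 41029275 to 41059525, Elane on chromosome 10 from 79886247 to 79888215 and Tcf4 on chromosome 18 from 69343356 to 69689079.

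After Dntt, the largest differences toward CLP were in Cox6a2 (6.12), Ccl4 (5.93), Sept1 (5.78), Gimap6 (5.59), Egr1 (5.50), Fos (5.36), Tsc22d1 (4.98), Il12a (4.88) and Ptprcap (4.87). Toward GMP, besides Elane, they were in Ctsg (-9.31), Prtn3 and Ms4a3 (both -8.33), Mpo (-7.51), Mt1 (-7.31), Anxa3 (-7.24), Hp (-7.18), F13a1 (-7.09) and Mgst1 (-6.64). Among early lymphoid genes 11 of 12 had higher values in CLP, with a median difference of 1.75 and Lck at 4.14, while Tcf3 was at -1.71. All 12 granule genes had lower values, with a median of -4.25, from Elane at -9.53 to Fcnb at -0.65. Elane was also detected in 93.3% of the pre-pro-B cells of this run, at a median of 11.2 TPM. Of 21 pDC genes 16 were higher in CLP, with a median of 0.54, Runx2 at 3.42 and Bst2 at -1.71; Bst2, Tcf3 and Cd79b had the other sign with the log2 of the mean TPM. All 11 monocyte genes, 15 S phase genes and 17 G2/M genes were lower in CLP, with medians of -1.87, -2.42 (undirected) and -2.76, and Cdk1 at -4.67; the median number of genes per cell was also lower, at 3280 in CLP and 5792 in GMP. Immediate-early genes, which respond within minutes to stimulation or handling, were higher in 12 of 13, with a median of 3.05. Of the B lineage genes 5 of 10 were higher, among them Blk (1.11) and Ebf1 (0.67), and Cd79b was at -1.95. Xist was detected without a Y-linked transcript in 29 of 51 GMP and 9 of 48 CLP cells, so the gates mixed the sexes unequally. In cells with a Y-linked transcript and no Xist the early lymphoid median was 1.72 and the granule median -4.02, and in cells with Xist alone they were 1.44 and -4.29.

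Within Ly6C- pre-DC, the comparison of SiglecH+ with SiglecH- cells asked how precursors that differ in a pDC surface protein differ in transcripts. Ly6c2, a transcript of the Ly6C protein, was at 1 TPM or more in 74.3% of SiglecH+ and 18.6% of SiglecH- cells. Its means were 510 and 18.8 TPM, so the gates were not matched in it. Tcf4 averaged 9.29 ± 1.78 (SD, 70 cells) in SiglecH+ and 2.34 ± 2.47 (SD, 70 cells) in SiglecH- cells, and Ly6d 10.80 ± 3.59 and 1.47 ± 2.44. Id2, an inhibitor of Tcf4-type factors that is high in cDC, ran the other way, at 2.49 ± 3.31 and 10.46 ± 2.95. Batf3, which cDC1 cells require, averaged 0.39 ± 1.70 and 5.08 ± 3.80, and Cd74, the MHC class II invariant chain, 3.67 ± 3.97 and 11.86 ± 2.21. Id2 lies on chromosome 12 from 25093799 to 25097140.

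Other genes highest in SiglecH+ cells were Cd7 (7.13), Cox6a2 (6.67), Runx2 (6.41), Sdc4 (6.32), Tfrc (6.17), Tex2 (5.86), Bst2 (5.23) and Cybb (4.84). Highest in SiglecH- cells, after Cd74 and Id2, were Plbd1 (-7.94), Ifi205 (-7.71), Anxa1 (-6.56), Lgals3 (-6.45), Aif1 (-6.24), Ccr2 (-6.14), Naaa (-5.83) and Anxa2 (-5.77). All 21 pDC genes had higher values in SiglecH+ cells, with a median of 2.44, though Irf7 (0.04) and Tlr9 (0.07) barely differed. Of 16 cDC genes 14 were lower, with a median of -1.07, while Cadm1 (0.64) and Havcr2 (0.58) were higher. All 7 MHC class II genes were lower, with a median of -8.19 and H2-Ab1 at -9.47, although both gates were sorted as negative for the protein. Early lymphoid genes were higher in 8 of 12, with a median of 1.19, led by Blnk, a B cell receptor adaptor (4.50), and Ighm (2.60). All 15 S phase genes were higher, with a median of 1.26, and Il7r was higher by 3.81. The G2/M median was 0.14, its direction not called here. Only 19 of the SiglecH+ cells shared a number run with the SiglecH- cells. Within it the pDC, cDC and MHC class II medians were 3.01, -0.97 and -6.24, and Irf7 (-0.10) and Tlr9 (-0.35) were lower in SiglecH+ cells.

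Within Ly6C+ pre-DC the same division by SiglecH gave a smaller median difference in pDC genes and a larger one in monocyte genes. Tcf4 averaged 8.76 ± 1.98 (SD, 45 cells) in SiglecH+ and 5.27 ± 3.32 (SD, 68 cells) in SiglecH- cells, and Irf8 8.34 ± 2.90 and 5.10 ± 3.69. Ly6d averaged 4.86 ± 4.23 and 0.41 ± 1.93. Lyz2, the lysozyme of monocytes and macrophages, averaged 1.70 ± 3.30 and 7.91 ± 3.64, and Ifitm3, an interferon-induced membrane protein gene, 3.33 ± 4.12 and 10.32 ± 2.74.

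Toward SiglecH+ the named genes went on with Tex2 (3.79), Cd200r1 (3.21), Cox6a2 (3.12, listed at 0 in SiglecH-), Pafah1b3 (2.68), Gpr171 and Csf2rb2 (both 2.61). Toward SiglecH- they went on with Ifitm2 (-4.79), Cd74 (-4.78), Wfdc17 (-4.77), Anxa1 (-4.72), Ccl6 (-4.61), F13a1 (-4.20), Ms4a4c (-4.10) and Cd209a (-3.99). Of 21 pDC genes 16 were higher in SiglecH+ cells, with a median of 0.62, while Irf7 was at -1.14. Monocyte genes were lower in 10 of 11, with a median of -1.99 and a mean of -2.16, Ly86 (0.40) being the exception. In Ly6C- cells 7 of 11 were lower, with a median of -0.058 (undirected) and a mean of -1.67, Lgals3 and Ccr2 being the lowest. Of 16 cDC genes 13 were lower, with a median of -0.45, and Mycl was at 1.19. Of 7 MHC class II genes 6 were lower, with a median of -2.18, and Id2 was at -2.61. Immediate-early genes were lower in all 13, with a median of -0.82, and interferon genes in 12 of 14, with a median of -0.24. These gates came from separate number runs, so gate and run cannot be told apart here. Across 7547 genes the SiglecH difference in Ly6C+ cells had a Pearson correlation of 0.44 and a Spearman correlation of 0.30 with that in Ly6C- cells. These correlations are across genes, which are not independent replicates. All 45 SiglecH+Ly6C+ and 51 of the SiglecH+Ly6C- cells shared a number run, so a difference between runs could also give a positive correlation.

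The comparison of pDC with SiglecH+Ly6C- pre-DC set the mature cell against the precursor nearest to it. Ly6d, Tcf4 and Irf8 were at similar levels, with differences of 0.15, 0.02 and 0.18. Ccr9, a homing receptor of pDC, averaged 7.65 ± 2.24 (SD, 27 cells) in pDC and 2.20 ± 2.72 (SD, 70 cells) in the pre-DC, and Klk1, a kallikrein protease gene, 5.30 ± 4.63 and 0.18 ± 1.09. Stmn1, a microtubule regulator of dividing cells, averaged 4.82 ± 4.51 and 9.33 ± 3.83, and Vim, the vimentin gene, 4.36 ± 3.31 and 8.81 ± 2.55.

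Toward pDC the named genes continued with D13Ertd608e (4.56), Cd74 (4.23), Fyn (3.54), Pltp (3.42), Khk (3.29), Lair1 (3.11), Krcc1 (2.86) and Cd164 (2.70). Toward the pre-DC they continued with Ranbp1 (-4.40), Etfb (-4.14), Anxa6 (-3.95), Atp5h (-3.63), Bex6 (-3.59), Trap1 (-3.57), Psma1 (-3.53) and Tecr (-3.49). Of 21 pDC genes 15 had higher values in pDC, with a median of 0.77, while Cd7 (-1.97) and Bcl11a (-0.61) were lower. All 15 S phase genes and all 17 G2/M genes were lower in pDC, with medians of -1.95 and -0.84 (the G2/M list undirected), from Mcm5 at -3.27 to Cdc20 at -0.09. MHC class II genes were higher in 5 of 7, with a median of 2.81; the pre-DC were sorted as negative for that protein and the pDC label does not name it. Monocyte genes were lower in 8 of 11, with a median of -0.50 (undirected) and Ms4a6c at -2.75. The gates came from separate number runs. Size factors shifted the median of all genes by 0.20 in this comparison.

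The comparison of pDC with CDP asked how far the progenitor was from the mature cell. Spib, a transcription factor of pDC and B cells, averaged 6.23 ± 3.27 (SD, 27 cells) in pDC and 0.75 ± 1.60 (SD, 58 cells) in CDP, and Tcf4 9.31 ± 2.26 and 7.01 ± 2.58. Cybb, the phagocyte oxidase subunit, averaged 7.80 ± 2.96 and 0.95 ± 1.75. Cdk6, a kinase of the G1 phase, averaged 3.10 ± 2.80 and 8.93 ± 2.25, and Ccnd2, its cyclin partner, 0.61 ± 1.22 and 5.66 ± 2.60.

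Other genes highest in pDC were Ccr9 (6.30), Ly6d (6.09), Klk1 (5.20), Cd74 (5.16), Ctsh (5.01), Lair1 (4.91), Ctsl (4.86) and Cd300c (4.74). Those highest in CDP, after Cdk6, were Ifitm2 (-5.64), Il12a (-5.59), Dhrs3 (-5.38), Emb (-5.37), Serpinb1a (-5.25), Bex6 (-5.19), Gpr97 (-5.08), Ccnd2 (-5.06) and Cmtm7 (-4.94). Of 21 pDC genes 20 had higher values in pDC, with a median of 2.64, and Bcl11a was at -0.09. Early lymphoid genes were lower in 8 of 12, with a median of -0.77 (undirected); Satb1 (-4.15) and Dntt (-3.72) were higher in CDP and Blnk (2.28) in pDC. Multipotency genes were lower in 9 of 12, with a median of -0.48 and Meis1 at -3.18. All 15 S phase genes were lower in pDC, with a median of -2.01, whereas G2/M genes were divided 9 to 8. Immediate-early genes were lower in 12 of 13, with a median of -1.60 and Fos at -4.33. In the run that held 24 of the pDC and all CDP the pDC list median was 2.25. Size factors shifted the median of all genes by 0.23.

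Compared with CLP, all 21 pDC genes had higher values in pDC, with a median difference of 2.04; Ccr9 (6.86) and Spib (5.88) were highest and Cox6a2 (0.62) and Tlr9 (0.54) lowest. Tcf4 averaged 9.31 ± 2.26 in pDC (SD, 27 cells) and 4.81 ± 3.32 in CLP (SD, 48 cells). Sdc4 (7.57) and Cybb (6.79) were also high in pDC, and Ier2 (-7.76), Cmtm7 (-7.16), Hist1h2ap (-8.16), Cdk2ap1 (-6.95) and Stmn1 (-6.82) in CLP. Dntt (-5.92) and Cnn3 (-6.34) were the lowest of the early lymphoid genes, of which 9 of 12 were lower, with a median of -0.73 (undirected). All 13 immediate-early genes were lower, with a median of -3.49, and 14 of 15 S phase genes, with a median of -1.68 (undirected). The gates came from runs that also differ in which genes were recorded at all: Calb1 (8.59) and Zfp260 (8.32) met the naming rule, and Calb1 was below 1 TPM in every cell of the CLP run. Size factors shifted the median of all genes by 0.27.

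Among SiglecH- pre-DC, monocyte genes were higher in Ly6C+ cells and most cDC genes in Ly6C- cells. Cd209a, a C-type lectin gene, averaged 9.97 ± 3.49 (SD, 68 cells) in Ly6C+ and 1.73 ± 3.56 (SD, 70 cells) in Ly6C- cells, and Id2 4.03 ± 4.29 and 10.46 ± 2.95. Cd7 (6.48), Ifitm2 (5.73), Ifitm3 (5.44) and S100a4 (5.13) were also highest in Ly6C+ cells, and Ifi205 (-5.39), Cd74 (-5.18), Batf3 (-4.32) and Ckb (-4.22) in Ly6C- cells. Monocyte genes were higher in 10 of 11, with a median of 2.10, F13a1 at 4.41 and Lgals3 at -0.28. The macrophage gene C1qb was found in 72.1% of Ly6C+ and 0% of Ly6C- cells, at a mean of 3.87 TPM in the former. Of 16 cDC genes 12 were lower, with a median of -0.79, although Cd209a (8.25) and Klf4 (2.51) belong to that list. MHC class II genes were lower in 6 of 7, with a median of -5.18. G2/M genes were higher in 15 of 17, with a median of 0.87, and pDC genes in 13 of 21, with a median of 0.54. The gates came from separate number runs.

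Among SiglecH+ pre-DC, Ly6d averaged 4.86 ± 4.23 (SD, 45 cells) in Ly6C+ and 10.80 ± 3.59 (SD, 70 cells) in Ly6C- cells. Sdc4 (-5.41), Ptprcap (-4.92), Cox6a2 (-3.90) and Herpud1 (-3.73) were also lower in Ly6C+ cells, and Cd209a (4.47), S100a6 (4.41), Ccr2 (4.12), Lgals3 (4.09) and Klf4 (3.18) were higher. Of 21 pDC genes 19 were lower in Ly6C+ cells, with a median of -0.55, while Tcf4 differed by -0.53. Monocyte genes were higher in 9 of 11, with a median of 1.27, and early lymphoid genes lower in 9 of 12, with a median of -1.04 and Blnk at -2.02. All 17 G2/M genes were higher, with a median of 1.06 and Ccnb1 at 2.22, whereas 14 of 15 S phase genes were lower, with a median of -0.69. In the number run that held both gates the pDC, monocyte and G2/M medians were -0.68, 1.56 and 1.14.

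Pre-pro-B cells, compared with CLP of the same run, had higher pDC genes and no directed difference in B lineage genes. Each gate held its own block of numbers in that run, so gate and block cannot be told apart. Ly6d averaged 14.05 ± 0.62 (SD, 30 cells) in pre-pro-B cells and 8.69 ± 3.88 (SD, 48 cells) in CLP, Siglech 10.64 ± 0.92 and 4.90 ± 3.74, and Bst2, an interferon-inducible antigen of pDC, 9.34 ± 2.88 and 4.15 ± 3.88. All 21 pDC genes had higher values, with a median of 2.39, from Bst2 (5.18) and Rnase6 (4.83) to Grm8 (0.14). Among B lineage genes 3 were higher and 3 lower of 10, with a median of 0.00. Early lymphoid genes were lower in 9 of 12, with a median of -0.85; Cnn3 was at -4.83 and Dntt at -3.62. D13Ertd608e (6.14), Ctsl (5.11) and Nucb2 (4.87) were also highest in pre-pro-B cells. Ier2 (-5.86), Egr1 (-5.70), Dusp2 (-5.45), Fos (-5.44) and Zfp36 (-5.42) were lowest, and all 13 immediate-early genes were lower, with a median of -3.42. All 17 G2/M genes were higher, with a median of 2.64. The S phase median was 0.11, its direction not called here, with Rrm2 at 1.82 and Mcm3 at -2.13. Xist without a Y-linked transcript was found in 20 of 30 pre-pro-B and 9 of 48 CLP cells; between those cells the pDC median was 2.75 and the B lineage median -0.67, and 4 of the 10 named genes were kept.

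In the comparison of cMoP with GMP the granule, monocyte and MHC class II lists were all undirected. Of 12 granule genes 10 were lower in cMoP, with a median of -1.03, Ctsg at -1.82 and Cebpe at -1.51, while Fcnb, a ficolin gene, was higher by 2.29. Of 11 monocyte genes 6 were higher, with a median of 0.15. Irf8 averaged 7.86 ± 1.21 (SD, 66 cells) in cMoP and 7.73 ± 1.94 (SD, 51 cells) in GMP, and Klf4, a transcription factor of monocytes, was higher by 2.26. MHC class II genes were higher in 6 of 7, with a median of 0.68. The gates came from separate runs, and the genes with the largest differences include Calb1 (8.48), which was below 1 TPM in every cell of the GMP run, and Zfp260 (7.14). The other named genes were Sept2 (6.30), Itpripl1 (6.13), Pfas (5.96), Taf10 (-6.92), Glrx5 (-6.67), Tgfb1 (-6.22), Ppp1r14b (-5.89) and Pgls (-5.67). Xist without a Y-linked transcript was found in 29 of 51 GMP, 9 of 48 CLP and 20 of 30 pre-pro-B cells and in 0 cells of the other gates, so sex differed here too, as between these 3 gates and LMPP or pDC. In cells with a Y-linked transcript and no Xist the granule and monocyte medians of cMoP against GMP were -0.66 and 0.13.

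Blood pre-DC, compared with the mean of the 4 marrow pre-DC gates, had low division genes and high monocyte genes. Stmn1 averaged 0.32 ± 1.27 (SD, 16 cells) in blood and 8.68 in marrow, and Top2a, the topoisomerase of dividing cells, 1.45 ± 2.06 and 6.24. All 15 S phase and 17 G2/M genes were lower in blood, with medians of -2.81 and -2.41. Hmgn2 (-5.52), Tuba1b (-5.25) and Cks1b (-4.68) were also lowest in blood. Lyz2 (6.39), Ifitm3 (5.58), Ifitm2 (5.49), Ccl6 (5.01) and Wfdc17 (4.89) were highest, and monocyte genes were higher in 10 of 11, with a median of 1.32. Of 21 pDC genes 20 were lower, with a median of -1.28, and Irf8 was at -4.32. The marrow gates differed in these genes, so the monocyte and pDC differences depend on the gates averaged. Irf8 averaged 3.67 ± 4.07 in blood and 5.10 ± 3.69 in SiglecH-Ly6C+ pre-DC, the marrow gate nearest in profile. Lyz2, Ifitm3, Ifitm2, Ccl6 and Wfdc17 were also named as higher in that gate than in SiglecH+Ly6C+ pre-DC. Immediate-early genes were higher in 11 of 13, with a median of 1.42, and 4 of 8 erythroid genes were higher, with Hba-a2 at 1.89. Tissue and number run cannot be told apart, and only 16 blood cells were measured. The median number of genes per cell was also lower, at 3648.5 in blood and 4177 to 4982.5 in the marrow gates. Of the blood cells 2 had under 2000 genes, and leaving such cells out shifted the median of all genes by 0.17.

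LMPP served as the starting population for CDP, CLP and GMP. All 12 multipotency genes had lower values in CDP and in CLP, with medians of -1.998 and -1.93, and 11 of 12 in GMP, with a median of -1.60. Meis1, a homeobox factor of stem cells, was at -4.61 in CLP and -5.45 in GMP, and Hlf at -3.57 in CDP. Car2, a carbonic anhydrase gene, averaged 9.70 ± 2.32 in LMPP (SD, 65 cells) and was the lowest named gene in all 3 comparisons, at -7.78 in CDP, -7.69 in CLP and -7.42 in GMP. Irf8 was higher in CDP by 6.64, in CLP by 6.55 and in GMP by 7.03. In CDP 19 of 21 pDC genes were higher, with a median of 1.36, and 10 of 12 early lymphoid genes, with a median of 1.72 and Ighm at 5.90. In CLP 11 of 12 early lymphoid genes were higher, with a median of 1.29, and 15 of 21 pDC genes, with a median of 0.64. In GMP all 12 granule genes were higher, with a median of 5.02, and 10 of 11 monocyte genes, with a median of 3.35. The S phase and G2/M medians of GMP were 3.40 and 3.35, their directions not called here. The median number of genes per cell was also higher, at 5792 in GMP and 3292 in LMPP.

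Named genes for CDP against LMPP were also Ly86 (7.09), Lgmn (7.06), Calb1 (7.05), Ifitm1 (-6.45), Ifitm3 (-4.56), Ctla2b (-4.43) and Eltd1 (-3.96). For CLP they were Ly6d (8.69), Cox6a2 (8.42), Pgls (7.06), Dntt (6.24), Sept2 (-7.49), Sod1 (-7.15), Actr2 (-6.75) and Cbx3 (-6.57). For GMP they were Elane (12.69), Ctsg (11.36), Mpo (9.84), Ms4a3 (9.33), Ap3s1 (9.04), Rgs1 (-6.97), Gimap6 (-6.86), Ctla2a and Pan3 (both -6.46). LMPP had a number run of its own, so its differences from the other gates and from their runs cannot be told apart.

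A CLP-to-GMP position was scored per cell from 50 genes highest in CLP and 50 highest in GMP, with 0 at the mean of held-out GMP cells and 1 at that of held-out CLP cells. Its median was 0.91 in pDC, 0.96 in CDP, 0.87 in SiglecH+Ly6C- pre-DC, 0.86 in pre-pro-B cells and 0.76 in LMPP. It was 0.72 in SiglecH+Ly6C+, 0.61 in SiglecH-Ly6C+, 0.62 in SiglecH-Ly6C- and 0.63 in blood pre-DC, and -0.01 in cMoP. All 27 pDC lay above 0.5 (interval 87.2 to 100%) and 0 of 66 cMoP did. In every other gate except GMP 93.75% or more of the cells also lay above 0.5, so that limit does not set pDC apart. A middle score arose with both gene sets low. In SiglecH-Ly6C- pre-DC the CLP genes averaged 2.12 and the GMP genes 1.58, against 6.02 and 2.23 in CLP and 2.44 and 7.33 in GMP. In pDC they averaged 3.96 and 1.01. Among the 50 CLP genes 8 belong to the immediate-early list and 3 to the pDC list. The genes and both ends of the scale came from the run of CLP, GMP and pre-pro-B cells. All other gates lie in other runs, so their positions cannot be told apart from differences between runs.

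**Figure D2:**
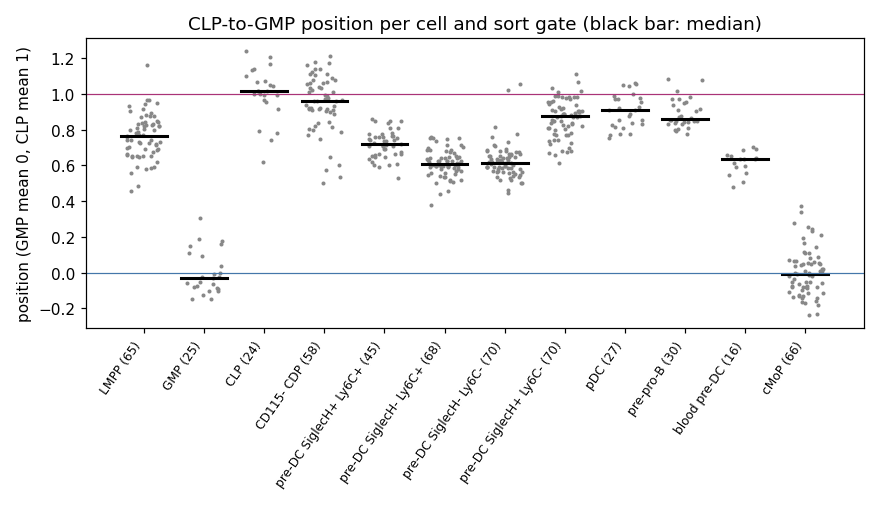
CLP-to-GMP position of each cell (vertical axis, 0 at the GMP mean and 1 at the CLP mean) by sort gate, with the number of scored cells in parentheses; points are cells and black bars are medians. For CLP (24 cells) and GMP (25 cells) only cells not used to choose the genes are drawn, and cMoP lies at the GMP end.

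By rank correlation of mean profiles across 12660 genes, pDC were nearest to SiglecH+Ly6C- pre-DC (0.85) and then to SiglecH+Ly6C+ pre-DC (0.81). CDP were also nearest to SiglecH+Ly6C- pre-DC (0.88), and blood pre-DC to SiglecH-Ly6C+ pre-DC (0.78). Pre-pro-B cells were nearest to CLP (0.90) and GMP to CLP (0.89), but these 3 gates share a number run. The correlation of pDC with pre-pro-B cells was 0.54 and with CLP 0.48, across runs.

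**Figure D3:**
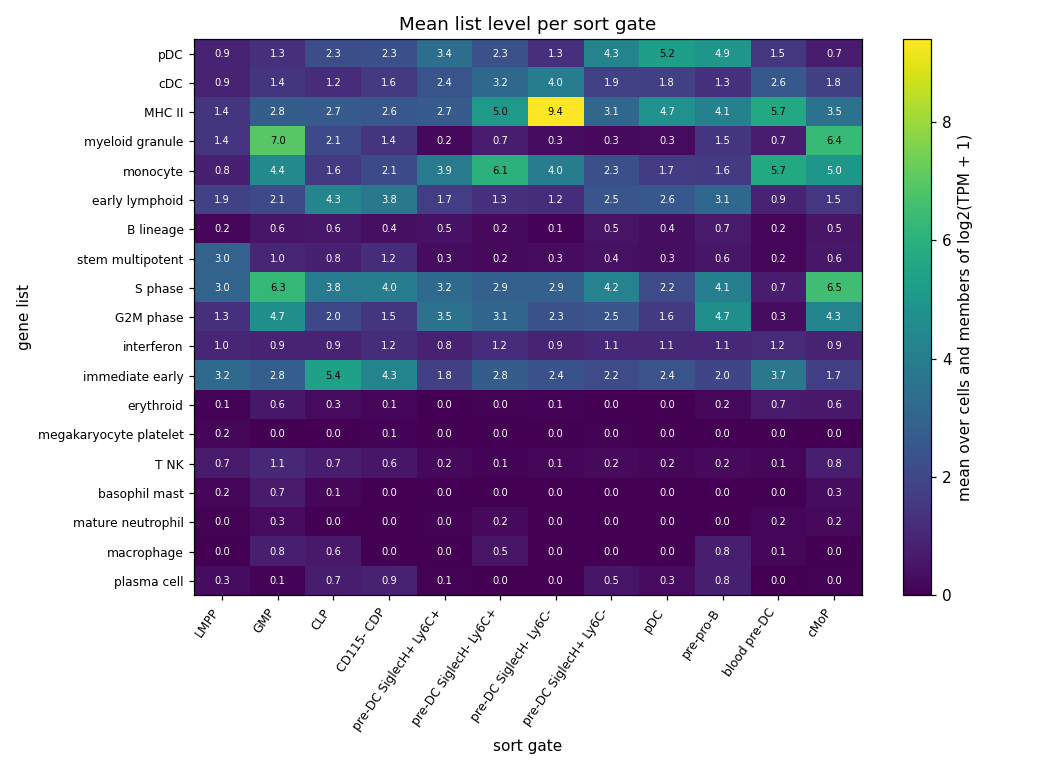
Mean level of each gene list (rows, mean over cells and members of log2(TPM + 1)) in each sort gate (columns); color and printed value give the level. The pDC list was highest in pDC (5.22) and the granule list in GMP (6.97).

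Markers of other cells were low in most gates. The macrophage list averaged 0.78 ± 0.51 in GMP, 0.65 ± 0.41 in CLP, 0.78 ± 0.47 in pre-pro-B cells and 0.50 ± 0.39 in SiglecH-Ly6C+ pre-DC (SD over cells), and at most 0.13 in the other gates. The erythroid list averaged 0.69 ± 1.71 in blood pre-DC, 0.64 ± 0.88 in cMoP and 0.62 ± 0.97 in GMP. The T and NK cell list was highest in GMP (1.06), through Nkg7, which averaged 8.41 there. Nkg7 also averaged 5.75 in CLP and 5.12 in LMPP, and Cd3g and Cd3d averaged 0.034 and 0 in GMP. The basophil and mast cell list was highest in GMP (0.67), as was the neutrophil list (0.28). The platelet list was highest in LMPP (0.17) and the plasma cell list in CDP (0.86). The B lineage list was highest in pre-pro-B cells (0.69 ± 0.79) and the interferon list in CDP (1.22 ± 0.72).

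Short genes were recorded unequally between library number runs. Among genes found in 10% or more of the cells of the other runs, all 104 under 100 nucleotides were below 1 TPM in every cell of the run of CLP, GMP and pre-pro-B cells, and 98.9% of 94 such genes in LMPP. Genes under 200 nucleotides took 4.51% of TPM in the median CDP cell and 0.140% in the median CLP cell.

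**Figure D4:**
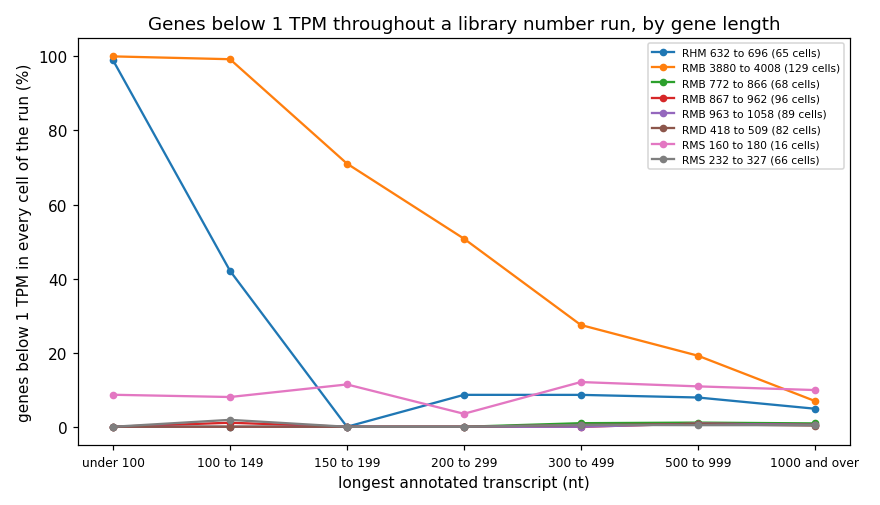
Percent of genes below 1 TPM in every cell of a library number run, among genes found in 10% or more of the cells of the other runs (vertical axis) by length of the longest annotated transcript in nucleotides (horizontal axis); each line is a run, labelled by its library numbers, and 1 run of 3 cells is not drawn. In the run of CLP, GMP and pre-pro-B cells 99.6% of genes under 150 nucleotides were below 1 TPM, against 6.98% of genes of 1000 nucleotides or more.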

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

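The threshold of 100 TPM, the omission of genes under 200 nucleotides, the subsets by Xist and Y-linked transcripts, the position without immediate-early genes and the omission of the GMP cells high in Ly6d were chosen after seeing the data. The other alternatives were planned. No paired analysis was possible because replicate numbers only name cells and no label links cells of different gates. A value counted as moved when it changed by at least 1 SD over cells, or left the interval of a share. Of 1510 recomputed differences of named genes 1410 stayed within 1 SD, 100 moved and 0 changed sign. These were the genes with the largest differences; of 554 values of the other reported focus genes and list members, recomputed later, 23 moved, 12 changed sign and the others stayed. Which genes were named depended most on averaging: the log2 of the mean TPM kept 52 of 190 named genes, against 157 and 153 with pseudocounts of 0.1 and 10, 186 with size factors and 190 without short genes. Size factors moved the median of all genes by over 0.1 in 3 contrasts, all with pDC, by up to 0.27. The log2 of the mean TPM moved it by -1.57 to 1.26. Of 229 values of the 29 main list results 209 stayed and 20 moved, none with a change of sign; of 1880 values of the other lists 107 moved. Of 532 list percentiles under other background genes 222 moved by 5 points or more. With background genes in 20% of cells 9 of 107 directions were lost and 21 gained, and with no filter 10 and 11; none turned, and all 24 directions among the main lists stayed. The causes of the changes that follow were not tested.

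With a pseudocount of 0.1 the granule median was -6.13 for CLP against GMP and 6.56 for GMP against LMPP, the pDC median 3.91 for pDC against CDP and 2.29 for CDP against LMPP, and the multipotency median -3.19, -3.17 and -2.79 for CDP, CLP and GMP against LMPP. With a pseudocount of 10 the granule medians were -2.33 and 2.76, the multipotency median of CLP against LMPP -0.90, the pDC median 1.40 for pre-pro-B against CLP, and the pDC and MHC class II medians 1.54 and -5.87 for SiglecH in Ly6C- pre-DC. With the log2 of the mean TPM the latter contrast had cDC and MHC class II medians of -2.33 and -3.20, Ly6C in SiglecH- pre-DC a monocyte median of 1.08, blood against marrow a G2/M median of -5.81, and GMP against LMPP a granule median of 3.60. The multipotency medians of CLP and GMP against LMPP were then -3.50 and -3.92.

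With the log2 of the mean TPM the differences of CLP against GMP became 2.23 for Irf8, 0.43 for Bst2, 0.039 for Tcf3 and 0.48 for Cd79b, that of Irf8 in cMoP against GMP -0.23, and those of Ly6d and Cdc20 in pDC against SiglecH+Ly6C- pre-DC -0.024 and 0.043. Cdc20 was 0.0032 with a pseudocount of 10. Irf7 for SiglecH in Ly6C- pre-DC was -0.20 with a pseudocount of 0.1 and -0.10 in the shared number run, where Tlr9 was -0.35, and Bcl11a in pDC against CDP was 0.62 with size factors.

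Some list medians changed sign, most of them near 0. The multipotency median of CLP against GMP, -0.001 as reported, was 0.0035 with a pseudocount of 0.1, 0.10 with the log2 of the mean TPM, 0.0016 without cells under 2000 genes and 0.065 in cells with a Y-linked transcript and no Xist. The G2/M median of pDC against CDP, 0.13 as reported, was -0.0032 with a pseudocount of 0.1 and -0.053 without the 5% of cells with the most genes. That of CDP against LMPP was -0.072 with a pseudocount of 10 and -0.30 with the log2 of the mean TPM, and the interferon median of pDC against CDP -0.11 with the latter. In cells with a Y-linked transcript and no Xist the multipotency and S phase medians of cMoP against GMP were 0.013 and -0.42.

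Ly6d shares depended on the threshold. At 10 TPM they were 84.3% in GMP, 37.9% in CDP, 46.7% in SiglecH+Ly6C+ and 8.57% in SiglecH-Ly6C- pre-DC, and 0% in blood pre-DC. At 100 TPM they were 3.92% in GMP, 60.4% in CLP, 29.3% in CDP, 28.9% and 5.71% in those pre-DC, and 0% in blood pre-DC and cMoP. Among the 2000 highest genes of a cell they were 3.92%, 72.9%, 31.03%, 33.3%, 7.14%, 0% and 0%. The position moved with ranks within the cell, to 0.91 in LMPP, 1.19 in CDP, 0.87 in SiglecH+Ly6C+, 0.715 in SiglecH-Ly6C- and 1.05 in SiglecH+Ly6C- pre-DC, 1.15 in pDC, 0.96 in pre-pro-B cells and -0.21 in cMoP. With 200 genes per side it was 0.69 in SiglecH-Ly6C+ and 0.72 in blood pre-DC, and with 20 genes 0.54 in blood pre-DC. Of 48 nearest profiles 43 stayed; pDC were nearest to SiglecH+Ly6C- pre-DC in every form tried. Depth is unknown in TPM, so a gene at 0 was not detected rather than absent.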

Other observations

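CLP and CDP each held cells with widely different Ly6d levels, which was not separated from uneven detection. In CLP 29 of 48 cells had Ly6d at 100 TPM or more and the lower quartile of the gate was 29.4 TPM, against an upper quartile of 4162 TPM. In CDP 13 of 58 cells had Ly6d at 1000 TPM or more, with a maximum of 14503 TPM. Of the CLP cells 8 (16.7%) had both Ly6d and Mpo at 100 TPM or more, against 23.9% from the product of the single shares. GMP held 2 cells with Ly6d above 1000 TPM, at 14619 and 6256 TPM. These cells had Siglech at 253 and 1580 TPM and Cox6a2 at 3981.51 and 1590 TPM, with Elane still at 1997 and 4316 TPM. Without them the early lymphoid median of CLP against GMP was 1.83 and the granule median -4.40.

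Of the tests that follow, 2 were set down before their results were seen, the correlation across genes in GMP cells and the comparison of pre-pro-B cells with pDC by cell cycle genes, as was a first measure of doublets that did not decide. The others were chosen after, among them the share of cells with both Ly6d and Siglech and the minimum of 5 genes for the test of carried-over reads.

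In the run of CLP, GMP and pre-pro-B cells, some genes abundant in other cell types were found at low level in many cells. Reads from macrophage libraries outside the series stay open as a source of part of this. Clec4f, Vsig4, Cd5l and Il18bp prompted that test and were left out of it; of 11 other macrophage genes (C1qa, C1qb and C1qc are also on the fixed macrophage list) 6 were present in 20% or more of the cells of all 3 gates, between the bounds set for either answer, and the C1q genes also in 22.1% to 72.1% of SiglecH-Ly6C+ pre-DC. Reads carried over between the 3 gates stay open. Genes of pre-pro-B cells were found in a median of 78.4% of GMP cells, against 4.55% of cMoP, but on only 3 genes, and genes of GMP in 80.0% of pre-pro-B cells against 14.8% of pDC on 9 genes (from 40% for Ms4a3 to 100% for Lyz2 and Mpo), which transcription in the cells of this run would also give. Transcription in GMP cells is not excluded either: across 120 genes the rank correlation of the GMP level with abundance in the other 2 gates was 0.45, between the bounds set for either answer.

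The pDC list averaged 4.91 ± 0.94 (SD, 30 cells) in pre-pro-B cells and 5.22 ± 1.23 (SD, 27 cells) in pDC, with 10 genes higher and 11 lower, and Tcf4 lower at 0.14 of the mean TPM in pDC. Carried-over reads are argued against as the whole cause, since the median ratio of mean TPM in pre-pro-B cells to pDC was 0.631, and it ran from 0.0128 for Grm8 to 14.9 for Pacsin1; Grm8, at 0.458 TPM in pre-pro-B cells, stays open. For Siglech, doublets with a pDC are argued against by 100% of the 30 cells holding it and Ly6d at 100 TPM or more. That measure was chosen after the values were seen, and Ly6d, itself high in this gate, adds little to it. The measure first planned was the share of cells with a list score above the lower quartile of pDC. It gave 76.7% and did not decide, so doublets stay open for the list itself. Libraries of sorted pDC labelled as pre-pro-B cannot be told apart from a difference between runs, because the gates share no run; the pDC of this series held 0 cells with Xist alone and pre-pro-B cells 20 of 30, so other mice would be needed. G2/M genes were higher in pre-pro-B cells by a median of 3.23. A pDC-like state of cells in this gate may also account for the pattern, and no test separated it from a wrong label.

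In the run of CLP, GMP and pre-pro-B cells 99.6% of genes under 150 nucleotides were below 1 TPM in every cell, against 6.98% of genes of 1000 nucleotides or more. This is consistent with a length limit from the reads or fragments of that run. Absence of these transcripts from early progenitors in general is argued against by CDP and cMoP, progenitors of other runs: of the 104 lost genes under 100 nucleotides 0% were below 1 TPM in every cell there. Absence from LMPP, CLP, GMP and pre-pro-B cells alone cannot be told apart from a limit of their runs: LMPP, another run, lacked 98.9% of 94 such genes, but LMPP are close to those gates, so the bound set for that test did not separate the causes. Length leaves some genes open: 88 genes were below 1 TPM in the whole run and in 20% or more of the cells of every other run of over 3 cells, and of 64 with a known length 16 were under 200 nucleotides.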
